A study of Homo sapiens with 14 samples.

How the data were processed

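RNA sequencing libraries of 7 colon adenomas and of the 7 normal mucosas matched to them, 1 library each, were compared. Per the labels' protocols, total RNA was extracted with TRIZOL and libraries were made with an Illumina TruSeq RNA kit. The submitters' processing notes name FastQC, Trimmomatic, TopHat2 2.0.10, HTSeq and DESeq2 and the genome build hg19. They do not say which step wrote the deposited tables, whose header has the column layout of a Cuffdiff gene table. Each deposited table holds 1 pair, with a value per feature for the normal mucosa and for the adenoma. These values are RPKM per the labels, which name the deposited tables so; the file headers name no unit for them. The normalization behind the RPKM values, and whether strand was used, are not given in the sources used here. The deposited tables also hold a log2 fold change, a p-value and a q-value by the authors and a yes or no call. The largest q-value of a call was 0.0488. A pair has 1 library per tissue, so these deposited p-values compare libraries, and they are only described.

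Groups and pairs come from the sample labels, and the pairing from the design text, which calls the samples matched. Pairs carry letters here. The deviations of the 2 libraries of a pair from their tissue means had a correlation over 0.1 in 5 of the 7 pairs. In 4 of the 7, the normal mucosa had a higher correlation with an adenoma of another pair than with its own, so the pairing rests on the design text and not on this check. No 2 libraries were near copies: the highest correlation between 2 libraries was 0.970, and at most 1 feature had the same value above 0 in both.

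The 7 tables list the same 25223 features. Left out were 28 features whose names a spreadsheet had turned into dates, 136 features (genes on chromosome Y, XIST and TSIX) and 122 features with a failed, too shallow or too deep status in any table, which left 24937. The tests used limma 3.58.1 in R 4.3.3 on log2(RPKM + 1). Genes needed an RPKM of at least 1 in at least 7 of the 14 libraries, which left 12372, among them 55 short structural RNAs of 2049 listed. The model held the pair as a block and the tissue, with trended empirical Bayes moderation, a two-sided test and Benjamini-Hochberg adjustment over all genes tested, at 0.05. Differences are adenoma minus normal mucosa on the log2(RPKM + 1) scale, which understates the change of low genes. Count-based tests were not run because the tables hold no counts.

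A total of 34 gene lists were fixed before the data were examined, with 437 distinct genes. Of these, 425 were found in the tables, 3 of them under an older symbol, and 12 were not, among them the 10 mitochondrially encoded genes. The 30 lists with at least 4 tested members were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, each adjusted over the lists. With camera and an estimated correlation 0 lists passed, and with fry 0. Lists overlap in part, as in the Wnt and stem cell lists. For each pair, a list's median was ranked among 10000 random lists matched on mean expression in 20 bins. The metallothionein genes, HSPA1A and HSPA1B, HBA1 and HBA2, and TPSAB1 and TPSB2 are near copies of each other, and genes in overlapping intervals may share reads, so their single values are uncertain.

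Genes were named by a rule fixed before the data were examined. It took up to 12 genes of either direction among those past the threshold with a mean RPKM of at least 5 and the same direction in 7 of 7 pairs, which gave 0, then the 3 tested members with the lowest adjusted p in each list, and PPARD, ALOX15, MYC, LGR5 and MKI67 in any case. Ties in adjusted p were broken by the unadjusted p. Immunoglobulin and T cell receptor segments, HLA genes, genes deleted in part of the population and features without an approved-style symbol were not named. Coordinates are the intervals of the deposited tables in hg19, counted from 1. The starts in the tables count from 0: of 1464 microRNA features, 573 had the annotated length as end minus start, and 1 as end minus start plus 1.

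Depth is not given in the tables. Where fragments are counted, low RPKM values of a gene are whole multiples of the worth of 1 fragment, so the most frequent ratio between 2 libraries among values in the lowest 0.3 of each gives their relative depth, in bins of 0.02 on the log2 scale. The step was tested on simulated counts. The relative depth of pair D's normal mucosa was within 0.25 (log2) of 12 of the 13 other libraries' ratios, and that library listed 11581 features at 0, against 5962 to 9809 in the others.

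The spread among adenomas was compared with that among normal mucosas by an exact permutation of tissue within pairs. Relations across pairs used exact permutations of the 7 pairs. The smallest p of the sign-flip test is 0.0156. Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter, an RPKM floor of 5, median centring, quantile normalization, no pair block, each pair left out, the sign-flip test, robust moderation, per-library weights, the other list tests, the median absolute deviation and list means. Keeping features with a failed status, leaving out short structural RNAs and leaving out pairs C and E were chosen after seeing the data. On data simulated for the comparison of adenoma with normal mucosa, 50 of 12372 genes were changed at each size. There limma called 48% at a log2 change of 1, 76% at 2, 98% at 3 and 94% at 4, with 8 false calls. The simulated noise was normal, independent between genes and, for each gene, of equal SD in all libraries, unlike the measured values. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used for the rest.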

Results

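Whole-transcriptome RNA sequencing was available for colon adenomas, benign glandular tumours of the large bowel, and for normal colonic mucosa from the same patients. There were 7 pairs, each with 1 adenoma and 1 normal mucosa library, so 14 libraries in all. The pairs are named A to G here. Expression was given as RPKM (reads scaled by feature length and sequencing depth) for 25223 features, in a separate table for each pair. Total read numbers per library were not used, because the tables hold no counts. The spacing of the lowest RPKM values gave each library's depth relative to the median library. Relative depth was between 0.345 and 1.86 in 13 libraries. The normal mucosa of pair D was far shallower, at 0.039, and its adenoma was 41.0 times deeper. A single fragment in that normal library was worth 25.7 times as much RPKM as in the median library, so low values there are coarse and a gene listed at 0 there may have been missed. Short structural RNAs (small nuclear, small nucleolar, micro, Y, vault, 7SK and similar RNAs) took between 6.93% and 31.1% of the summed RPKM in the 10 libraries of pairs A, B, D, F and G. Their share was 73.4% in the normal mucosa and 74.9% in the adenoma of pair C. It was 93.7% and 91.8% in the normal mucosa and adenoma of pair E. After filtering, 12372 genes were tested.

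**Figure D1:**
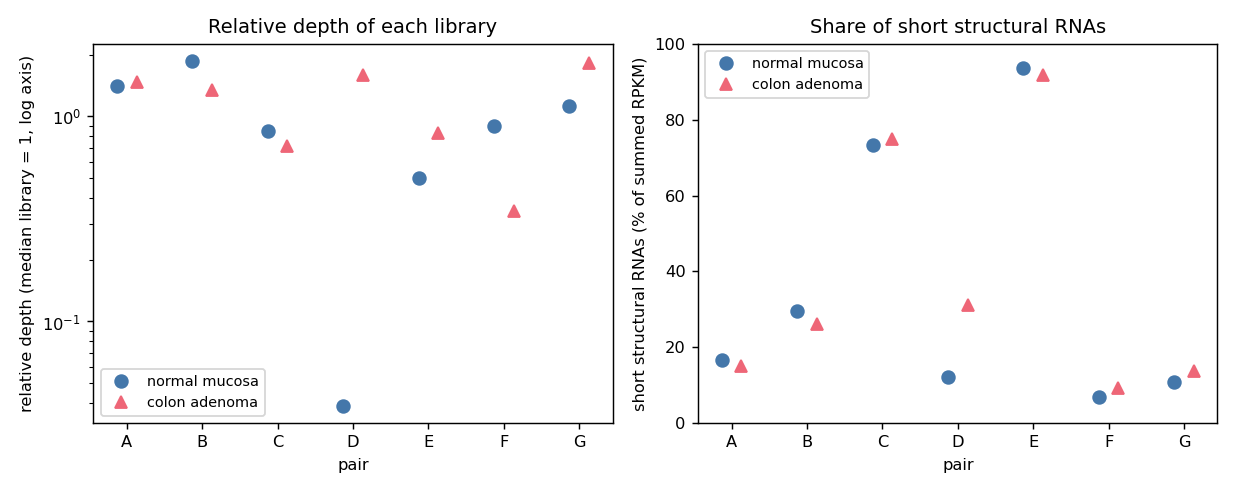
The left panel shows the depth of each library relative to the median library on a log axis, and the right panel the percentage of summed RPKM taken by short structural RNAs, for the normal mucosa (circles) and the adenoma (triangles) of each pair. The normal mucosa of pair D lies at a relative depth of 0.039. In the 4 libraries of pairs C and E, short structural RNAs took between 73.4% and 93.7% of the summed RPKM.

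The comparison of adenoma with matched normal mucosa asks which genes differ in expression between the tumour and the normal mucosa paired with it. Matched samples need not come from the same site in the bowel, and a difference of site within pairs was not tested. PYY, the gut hormone peptide YY (chromosome 17, 42030106 to 42081837, hg19), was lower in the adenoma of 7 of 7 pairs. It was listed at 0 in the adenomas of pairs D and G. It averaged 28.6 ± 29.4 RPKM in normal mucosa and 5.24 ± 6.54 RPKM in adenoma (SD, n = 7), a log2 difference of -2.24 (SE 0.50, limma adjusted p = 0.861). NFE2L3, a CNC-family transcription factor (chromosome 7, 26191847 to 26226757), was higher in 7 of 7 pairs, at 5.28 ± 1.68 RPKM in normal mucosa and 18.3 ± 14.9 RPKM in adenoma. Its log2 difference was 1.35 (SE 0.39, limma adjusted p = 0.861). PTGER2, a prostaglandin E2 receptor gene (chromosome 14, 52781016 to 52795324), was higher in 6 of 7 pairs, at 2.14 ± 0.948 against 4.86 ± 2.98 RPKM, with a log2 difference of 0.77 (SE 0.24, limma adjusted p = 0.861). TRIB3, a pseudokinase gene, and PROX1, a homeobox gene, were also higher in 7 of 7 pairs, with log2 differences of 0.87 (SE 0.35) and 0.65 (SE 0.27). TRIB3, however, had 0.964 RPKM in both tissues of pair C. PROX1 was low, with 0.531 against 0.599 RPKM in pair F, and was listed at 0 in the shallow normal mucosa of pair D. All of these genes were named for the lowest adjusted p in their lists, so their agreement across pairs is no separate evidence.

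None of these differences passed the threshold. By limma with the pair as a block, 0 of 12372 genes were higher and 0 were lower at adjusted p 0.05, so 0 were higher or lower by 2-fold as well. At an unadjusted p under 0.05, 125 genes were higher and 124 were lower. The smallest adjusted p was 0.861. An exact sign-flip permutation test of the within-pair differences also called 0 genes, with 230 higher and 77 lower at an unadjusted p under 0.05, and so did robust moderation and per-library weights. In data simulated with each gene's residual SD, the limma test called 48% of genes changed by 1 on the log2 scale and 76% of those changed by 2. That noise was independent between genes and equal across pairs, whereas the measured changes were wider in pairs D and G. These shares therefore may not hold for the measured data. Leaving out pair E lowered the smallest adjusted p to 0.0968, still with 0 calls.

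**Figure D2:**
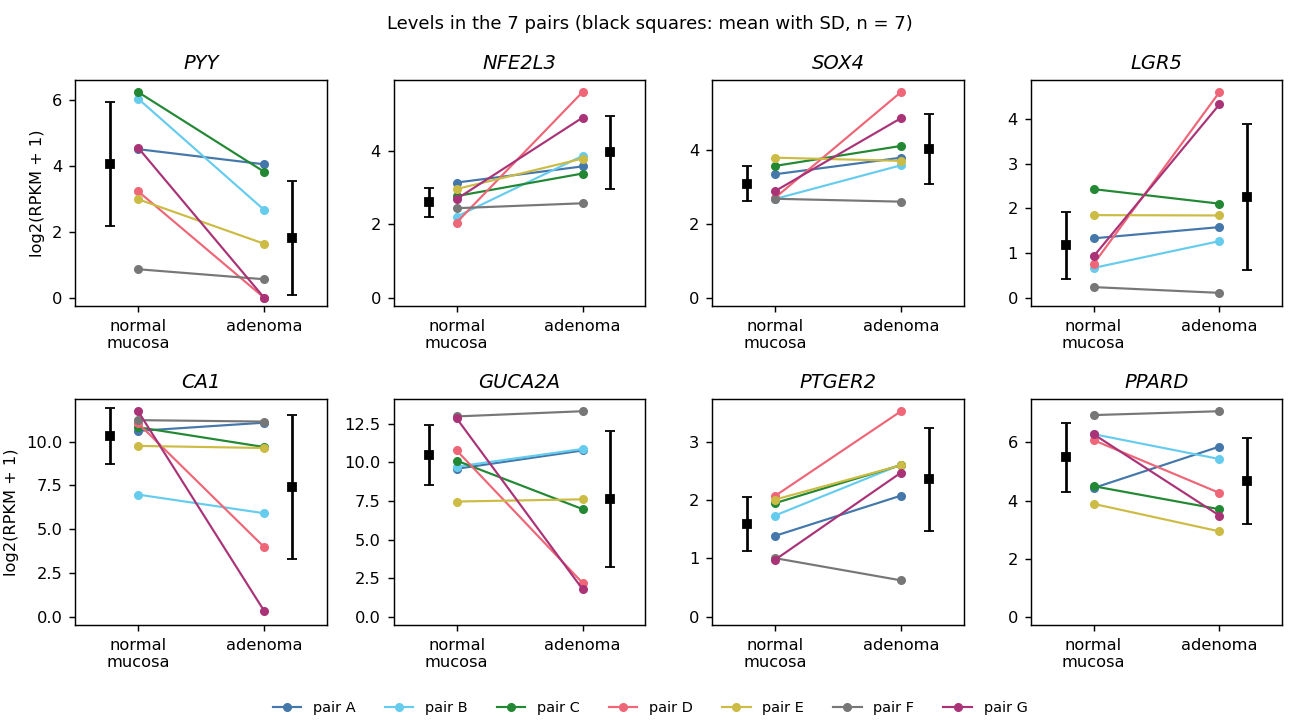
Levels of 8 genes on the log2(RPKM + 1) scale in the normal mucosa and adenoma of each pair, 1 line per pair, with the mean and SD over the 7 pairs as black squares and bars. PYY is lower in 7 of 7 pairs and NFE2L3 higher in 7 of 7, while CA1 has 0.271 RPKM and GUCA2A 2.46 RPKM in the adenoma of pair G.

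Genes of absorptive colonocytes, the surface cells that take up salt and water, were lower in adenoma as a list, and the size of the difference varied widely between pairs. The median log2 difference of the 20 tested members was -7.34 in pair G, -6.02 in pair D, -1.51 in pair C and -0.49 in pair E. It was above 0 in the other pairs, at 0.36 in F, 0.69 in B and 1.80 in A. CA1, a carbonic anhydrase gene (chromosome 8, 86240458 to 86290342), had 3412 RPKM in the normal mucosa of pair G and 0.271 RPKM in its adenoma, and 2119 against 14.9 RPKM in pair D. In pair F it had 2395 against 2265 RPKM. GUCA2A, which encodes the peptide guanylin, had 7392 against 2.46 RPKM in pair G and 1748 against 3.59 RPKM in pair D, but 8021 against 10135 RPKM in pair F. Over the 7 pairs, the log2 difference was -2.91 (SE 1.37) for CA1, -2.85 (SE 1.51) for GUCA2A and -3.05 (SE 1.41) for GUCA2B, which encodes uroguanylin. CA1 was lower in 6 of 7 pairs, but GUCA2A and GUCA2B were each higher in 4 of 7. None of the 20 members passed the test over all genes or adjusted over the list alone. The list's median difference was -1.59 (camera adjusted p = 2.63e-09 with a preset correlation), and the call was lost with an estimated correlation (adjusted p = 0.544). With limma's per-library weights the median was 0.23. These weights were equal within each pair and lowest for pairs D and G, which had the widest changes.

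Genes of BEST4-positive epithelial cells, a minor absorptive cell type, had medians of -6.87 in G, -4.23 in D, -1.08 in C, -0.62 in B, -0.39 in E, 0.51 in A and 1.11 in F. In pair B the medians of the absorptive and BEST4 lists thus had opposite signs, but the BEST4 list was split there, with 2 members higher and 3 lower. The list median was -1.53 over 5 tested members (camera adjusted p = 0.000345, and adjusted p = 0.544 with an estimated correlation). CA7, another carbonic anhydrase gene, had 180 against 0.545 RPKM in pair G and 203 against 0.413 RPKM in pair D. SPIB, a transcription factor gene, was lower in 6 of 7 pairs, with a log2 difference of -1.58 (SE 0.72). Genes of aldosterone-responsive sodium transport had a median of -0.46 (camera adjusted p = 0.00111, and adjusted p = 0.544 with an estimated correlation). Without pair G this median was -0.11 and the call was lost (camera adjusted p = 0.143). SCNN1B, a subunit of the epithelial sodium channel, had 129 RPKM in the normal mucosa and 0.212 RPKM in the adenoma of pair G, and NR3C2, the mineralocorticoid receptor gene, had 52.2 against 8.21 RPKM there. Metallothionein genes, which bind zinc and copper, had a median of -1.32 (camera adjusted p = 3.28e-05, and adjusted p = 0.544 with an estimated correlation). Their median was -5.26 in pair G and -4.78 in pair D, but 2.10 in pair B. These genes are near-identical copies, so the values of single members such as MT1G, with 453 ± 537 RPKM in normal mucosa and 248 ± 353 RPKM in adenoma (SD, n = 7), are uncertain. With per-library weights the calls of these 3 lists were lost, at medians of -0.30 for the BEST4 list (camera adjusted p = 0.405), 0.07 for sodium transport and 0.14 for metallothioneins.

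Target genes of Wnt signalling passed as higher only at the preset correlation of 0.01, with a median of 0.83 over 15 tested members (camera adjusted p = 1.8e-06). The correlation estimated among members was 0.86, and with it the call was lost (camera adjusted p = 0.544). The list median was above 0 in 3 pairs and below 0 in 4. The medians were 3.46 in pair D, 2.94 in pair G and 0.91 in pair B, and between -0.75 and -0.01 in the other pairs. Crypt base stem cell genes had a median of 0.82 (camera adjusted p = 0.000345, and adjusted p = 0.544 with an estimated correlation), with 2.96 in pair D and 3.09 in pair G. They were 0.82 in B and 0.19 in C, and below 0 in the other pairs, at -0.65 in F, -0.20 in E and -0.11 in A. Without pair D the stem cell median was 0.48 and the call was lost (camera adjusted p = 0.0685). LGR5, a stem cell receptor gene (chromosome 12, 71833813 to 71978622), had 0.682 against 23.2 RPKM in pair D and 0.895 against 19.0 RPKM in pair G, but 4.38 against 3.29 RPKM in pair C. Its log2 difference was 1.09 (SE 0.55, limma adjusted p = 0.861). SOX4 and SOX9, transcription factors of progenitor cells, had log2 differences of 0.94 (SE 0.36) and 0.98 (SE 0.46). MYC (chromosome 8, 128748315 to 128753680) had 3.81 against 89.7 RPKM in pair G and 48.8 against 23.3 RPKM in pair A, and a log2 difference of 0.75 (SE 0.56, limma adjusted p = 0.861). The normal mucosa of pair D, whose relative depth was 0.039, supplied the low values of that pair. No member of either list passed the test over all genes or adjusted over the list alone.

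A list of genes reported elsewhere as high in colorectal adenoma had a median of 1.14 over 10 tested of 20 members (camera adjusted p = 1.98e-05, and adjusted p = 0.544 with an estimated correlation). The pair medians were 2.79 in D, 2.76 in G, 1.26 in B, 0.32 in E and 0.21 in A. They were below 0 in C, at -0.04, and in F, at -0.43. Beside NFE2L3 and TRIB3, ETV4, an ETS-family transcription factor gene, was higher in 6 of 7 pairs, at 2.12 ± 2.10 RPKM in normal mucosa and 17.1 ± 24.9 RPKM in adenoma (SD, n = 7), with 5.27 against 68.4 RPKM in pair D and 0.182 against 30.2 RPKM in pair G. With per-library weights the calls of the Wnt, stem cell and adenoma lists were lost, at medians of 0.18, 0.15 and 0.24.

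The lists of proliferation genes had their highest medians in pair G. The median of the G2/M cell cycle genes was 2.73 in pair G and between -0.48 and 0.34 in the 6 other pairs. Small differences in those pairs also lay at the edge of random lists, at percentile 99.5 in pair A and 99.3 in pair B, and at 0.6 in pair E and 0.27 in pair F. In pair A the DNA replication, ribosome biogenesis and nucleotide synthesis lists lay at the opposite edge, with medians of -0.39, -0.37 and -0.29 and 0 members higher. MKI67, a marker of cycling cells (chromosome 10, 129894923 to 129924468), had 0.726 against 9.69 RPKM in pair G, and over the 7 pairs 12.01 ± 14.5 RPKM in normal mucosa and 11.5 ± 10.1 RPKM in adenoma (SD, n = 7). TOP2A, the mitotic topoisomerase gene, had 0.880 against 20.3 RPKM in pair G, and normal mucosas spanned 0.662 to 26.4 RPKM. CCNB2, a cyclin gene, had 2.88 against 19.5 RPKM there, and normal mucosas spanned 2.50 to 24.8 RPKM. For both, pair G joined a normal mucosa near the low end to an adenoma within the range of normal mucosas. For PPAT and SHMT2 of the nucleotide list, the adenoma of pair G lay above every normal mucosa, at 7.26 and 51.7 RPKM. The G2/M list median was 0.39 (camera adjusted p = 0.00126, and adjusted p = 0.736 with an estimated correlation), and without pair G it was 0.03 (camera adjusted p = 0.729). Ribosome biogenesis genes had a median of 0.28 (camera adjusted p = 0.00635, and adjusted p = 0.736 with an estimated correlation), with 2.31 in pair G and 0.92 in pair D. The ribosome biogenesis median was below 0 in the 5 other pairs, between -0.37 in A and -0.02 in C. Without pair G this median was 0.02 (camera adjusted p = 0.822), without pair D it was 0.19 (camera adjusted p = 0.0685), and with per-library weights it was -0.20, past the threshold in the other direction (camera adjusted p = 0.00464). DNA replication genes (median 0.21, camera adjusted p = 0.115) and nucleotide and polyamine synthesis genes (median 0.32, camera adjusted p = 0.119) passed no threshold. Their medians in pair G were 1.95 and 2.72, and with per-library weights they were -0.13 and -0.21, both past the threshold as lower (camera adjusted p = 0.00464). Both passed as higher without pair A, at 0.32 (camera adjusted p = 0.0173) and 0.41 (camera adjusted p = 0.0318), and without pair F, at 0.34 and 0.45 (camera adjusted p = 0.028 for each).

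Enteroendocrine genes, which encode gut hormones, were lower in 6 of 7 pairs. The median over 5 tested members was -1.64 (camera adjusted p = 1.81e-05, and adjusted p = 0.544 with an estimated correlation). Adjusted over the list alone, 3 of the 5 members were lower, against 0 over all genes tested. These were PYY, INSL5 and GCG. INSL5, an insulin-like peptide gene (chromosome 1, 67263424 to 67266942), averaged 19.0 ± 21.0 RPKM in normal mucosa and 1.15 ± 1.45 RPKM in adenoma (SD, n = 7), with a log2 difference of -2.49 (SE 0.83). GCG, the proglucagon gene, had a log2 difference of -1.38 (SE 0.50). Both were lower in 6 of 7 pairs, with pair E the exception. The median of goblet cell genes, of the mucus-secreting cells, ran from -1.84 in pair D to 2.10 in pair A, and the list passed no threshold (median -0.45, camera adjusted p = 0.0551). Without pair A it was -0.81 and passed (camera adjusted p = 0.00154), as it did without pair F at -0.68 and without pair G at -0.63. These are the 3 pairs in which the goblet median was above 0, so leaving 1 of them out pulls the list lower in any case. With a pseudocount of 5 the goblet list passed too, at -0.35 (camera adjusted p = 0.0297). Pan-epithelial genes such as KRT19 and CDX1 had a median of -0.40 (camera adjusted p = 0.000849, and adjusted p = 0.544 with an estimated correlation). Without pair G the median was -0.24 (camera adjusted p = 0.0588), and with quantile normalization it was -0.24 as well (camera adjusted p = 0.0711). Paneth cell and REG genes (median 0.10) and gastric and serrated-type genes (median 0.07) passed no threshold, and their means and tests pointed lower while their medians were above 0. With per-library weights the gastric list passed as lower, at -0.58 (camera adjusted p = 0.0213). PLA2G2A, a secreted phospholipase gene of the Paneth list, was lower in 6 of 7 pairs, with a log2 difference of -1.47 (SE 0.53).

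Smooth muscle genes were lower in 5 of 7 pairs, with a median of -1.01 over 12 tested members (camera adjusted p = 4.14e-05, and adjusted p = 0.544 with an estimated correlation). The pair medians ran from -3.21 in B and -2.60 in A to 0.43 in D and 2.80 in E. ACTG2, the enteric smooth muscle actin gene, had 190 against 8.36 RPKM in pair B and 0.730 against 21.8 RPKM in pair E. Fibroblast and matrix genes had a median of -0.10 (camera adjusted p = 0.371), with 2.37 in pair E, 1.82 in pair D and -2.07 in pair F. The fibroblast list passed without pair E, at -0.45 (camera adjusted p = 0.000492), and without pair D, at -0.43 (camera adjusted p = 0.00441). With per-library weights it passed at -0.99 (camera adjusted p = 9.4e-09). Endothelial cell genes (median 0.12, camera adjusted p = 0.499) passed no threshold, but with per-library weights they passed as lower, at -0.33 (camera adjusted p = 0.0112). PLVAP, an endothelial membrane protein gene, was higher in 6 of 7 pairs with a log2 difference of 0.66 (SE 0.36).

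Macrophage genes were lower in 6 of 7 pairs, with a median of -0.59 over 9 tested members (camera adjusted p = 0.00075, and adjusted p = 0.544 with an estimated correlation). The median was -3.15 in pair C and 2.08 in pair E. TYROBP, a myeloid adaptor gene, had 29.7 against 2.45 RPKM in pair C. Without pair C the macrophage median was -0.13 (camera adjusted p = 0.0982), and with quantile normalization it was -0.40 (camera adjusted p = 0.0607). Immediate early and heat shock genes, which respond to handling and stress, had a median of -0.40 (camera adjusted p = 0.00482, and adjusted p = 0.544 with an estimated correlation). DUSP1 had 190 against 3.85 RPKM in pair D and 112 against 4.68 RPKM in pair G. The call of this list was lost without pair D at -0.11, without pair C at -0.29 and with quantile normalization at -0.24. T and NK cell genes were just outside the threshold (median -0.38, camera adjusted p = 0.0505), and passed without pair B, D or E, at -0.35, -0.57 and -0.72. They also passed with a pseudocount of 5, at -0.18, with no filter, at -0.30, with short structural RNAs left out, at -0.38, and without pairs C and E, at -0.77 (camera adjusted p = 0.00379). Plasma cell genes (median -0.06), mast cell genes (median 0.14), interferon response genes (median -0.04) and neutrophil and inflammatory chemokine genes (median 0.45, mean 0.00, tested direction lower) passed no threshold, although the neutrophil list passed without pair G, at -0.31 (camera adjusted p = 0.0233). Plasma cell genes passed without pair E, at -0.59 (camera adjusted p = 0.00203), and interferon genes without pair D, at -0.34 (camera adjusted p = 0.00121). Enteric neuron and glia, B cell and red blood cell lists had 2, 3 and 2 tested members and were not tested as lists. HBB, a haemoglobin gene, was higher in 6 of 7 pairs, with a log2 difference of 1.03 (SE 0.43, limma adjusted p = 0.861).

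PPARD, a lipid-activated nuclear receptor gene (chromosome 6, 35310335 to 35395968, an interval shared with another feature), averaged 56.9 ± 39.9 RPKM in normal mucosa and 40.0 ± 45.4 RPKM in adenoma (SD, n = 7). It was lower in 5 of 7 pairs, with a log2 difference of -0.81 (SE 0.43, limma adjusted p = 0.861). ALOX15, a lipoxygenase gene, lay below the filter, at 0.266 ± 0.283 RPKM in normal mucosa and 0.106 ± 0.103 RPKM in adenoma, and was not tested. The prostaglandin and lipoxygenase list had a median of 0.06, a mean of -0.15 and a tested direction of lower (camera adjusted p = 0.371). With no filter on low values it passed, at -0.080, and with per-library weights at -0.10 (camera adjusted p = 0.0188). PTGS1, which encodes cyclooxygenase 1, was lower in 6 of 7 pairs, with a log2 difference of -0.60 (SE 0.27), while PTGER2 was higher in 6. MAPK output genes (median 0.22, camera adjusted p = 0.762) held genes of both directions. DUSP5, a MAPK phosphatase gene, had a log2 difference of -1.48 (SE 0.59). Fatty acid oxidation and ketogenesis genes had a median of -0.11 (camera adjusted p = 0.164), and passed without pair B, at -0.24 (camera adjusted p = 0.00457), and without pairs A and F in turn, at -0.24 and -0.18. With per-library weights it was 0.29, past the threshold as higher (camera adjusted p = 0.000977). Glycolysis and hypoxia genes had a median of -0.19 (camera adjusted p = 0.0716), and passed without pair A, at -0.26 (camera adjusted p = 0.0054).

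**Figure D3:**
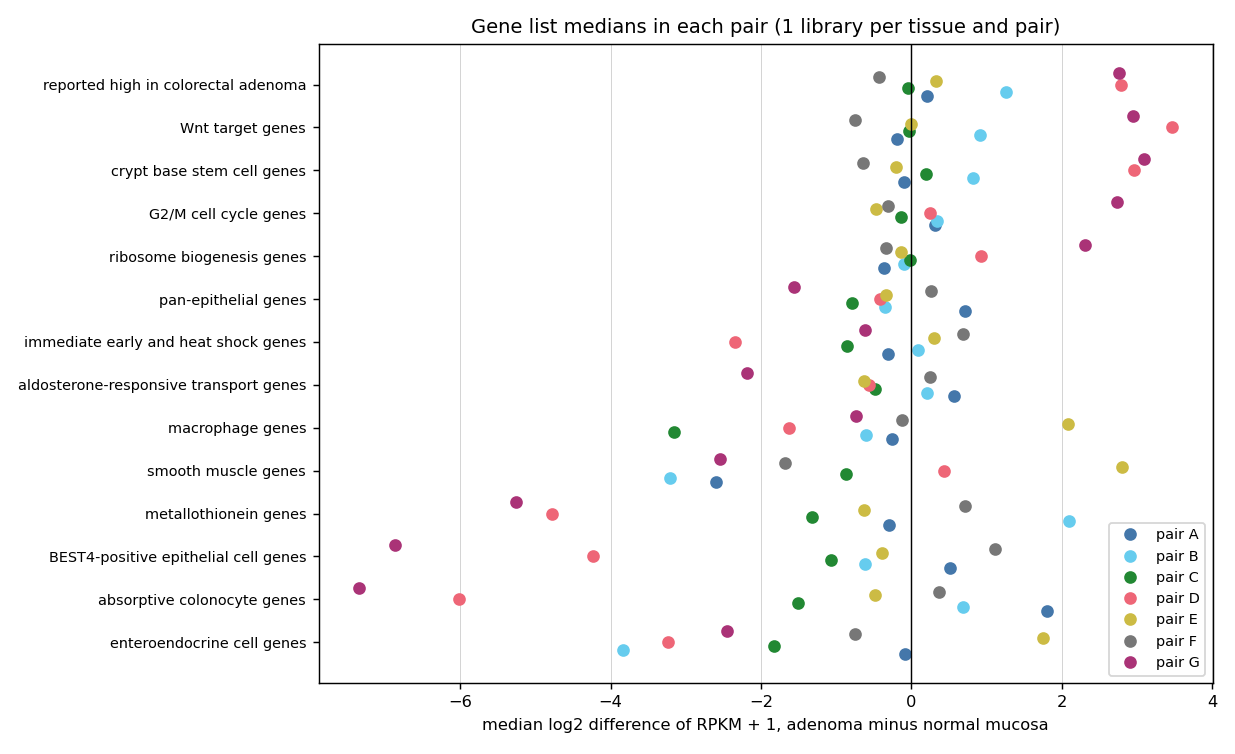
Median log2 difference of RPKM + 1 (adenoma minus normal mucosa) over the tested members of each of the 14 lists that passed camera with a preset correlation, 1 point per pair. The points of pairs D and G lie at 3.46 and 2.94 for Wnt target genes and at -6.02 and -7.34 for absorptive colonocyte genes, apart from those of the other pairs.

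Pairs differed in how far adenoma and normal mucosa lay apart. The SD of the log2 differences over the 12372 genes was 1.49 in pair D and 1.39 in pair G, against 0.533 to 0.731 in the 5 other pairs. In pair D, 44.4% of genes differed by at least 2-fold, in pair G 40.1%, and in pair F 6.05%. With 1 library per tissue within a pair, these are differences between 2 libraries with no replicate check. Against 10000 random lists of the same size and mean expression, the Wnt target median lay at percentile 100 in pairs B, D and G and at percentile 0 in pair F. The absorptive colonocyte median lay at percentile 0 in pairs C, D and G and 0.03 in pair E, and at percentile 100 in pairs A and B and 99.9 in pair F.

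The authors' deposited tables call genes within each pair. Leaving out genes on chromosome Y, XIST, TSIX and features with a failed test, the authors' deposited table called 57 genes in pair A, 88 in B, 33 in C, 230 in D, 21 in E, 69 in F and 32 in G. In pair D, 228 of the calls were higher in adenoma and 2 were lower, in the pair whose normal mucosa library was the shallowest. In pair F, 62 were lower and 7 higher, and in pair B 64 were lower and 24 higher. Of 464 genes called in at least 1 pair in the authors' deposited tables, 410 were called in 1 pair, 42 in 2 and 12 in 3, with 0 called in 4 or more. The smooth muscle genes DES and MYH11 and the contractile and cytoskeletal genes MYL9 and FLNA were called lower in pairs A, B and F by the authors' deposited tables. DES had 37.4 against 3.01 RPKM in pair A, 160 against 7.65 in pair B and 256 against 82.9 in pair F. A2M, FN1, ITLN1 and TFF1 were each called in 3 pairs of the authors' deposited tables, but not in 1 direction. TFF1, a trefoil peptide gene, had 51.9 against 470 RPKM in pair A and 4623 against 176 RPKM in pair B. PRAC was called lower in pairs A and B and higher in pair E. It had 160 against 0 RPKM in A, 107 against 0 in B and 0 against 57.8 in E. Without a call, it had 598 against 0.213 RPKM in D, 69.8 against 408 in G and 117 against 114 in F. Pairs D and G shared 4 calls of the same direction in the authors' deposited tables, where 0.182 would be expected of independent lists. That expectation takes all genes as equally likely to be called, so an excess over it is no test of agreement. The 4 shared genes were KLK6, KLK11, SLCO1B3 and TCN1, all higher in adenoma. All were listed at 0 in the normal mucosa of both pairs, and that of pair D was shallow. TCN1, a vitamin B12 carrier gene, was listed at 0 in the normal mucosa of both pairs and had 18.9 RPKM in the adenoma of pair D and 31.4 RPKM in that of pair G. The genes of this paragraph were chosen after their values were seen.

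Adenomas did not differ among themselves measurably more than normal mucosas did. The median over genes of the log2 ratio of the SD among adenomas to the SD among normal mucosas was 0.01 (two-sided exact permutation test over the within-pair swaps, p = 0.938, n = 7). The median SD was 0.725 among adenomas and 0.700 among normal mucosas on the log2(RPKM + 1) scale, and 51.0% of genes were more spread among adenomas. How the tables of the pairs were scaled to each other is not given, and with each library centred on its median the ratio was -0.0226. The normal mucosas include the shallow library of pair D (relative depth 0.039), whose coarse values may add to their SD. Both groups hold pairs C and E, so the structural RNA difference between pairs enters both SDs. With single pairs left out the ratio ran from -0.15 to 0.11.

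Pairs with higher Wnt target genes had lower absorptive colonocyte genes, but the relation rested on pairs D and G. Across the 7 pairs, Pearson's r was -0.892 (exact permutation p = 0.0274, adjusted over 3 relations 0.0821) and Spearman's rho was -0.643 (exact permutation p = 0.139, adjusted 0.302). Without pairs D and G, the pairs farthest from the median, r was 0.02 over the remaining 5. For Wnt target and G2/M genes, r was 0.647 (exact permutation p = 0.103, adjusted 0.154) and rho was 0.464 (exact permutation p = 0.302, adjusted 0.302), with r at 0.554 without pairs D and G. Without pair D alone r was 0.940 (exact permutation p = 0.0333). For absorptive colonocyte and fibroblast genes, r was -0.388 (exact permutation p = 0.387, adjusted 0.387) and rho was -0.464 (exact permutation p = 0.302, adjusted 0.302), with r at -0.185 without pairs D and G. None of the 3 relations passed after adjustment. Within the structural RNA batch, pairs C and E are too few for a value of their own. Over the 5 other pairs r was -0.922 for Wnt target and absorptive genes (exact permutation p = 0.0667).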

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

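All tests of explanations here except that on well measured genes were chosen after the result was seen. Of the sets of 7 within-pair differences examined, those of 98 named genes and 30 lists, 10 (7.81%) held a value far from the 6 others. Chance puts about 5% of sets past the limit where sets are independent and their 7 values have equal variance. Here lists and named genes overlap and pairs D and G were wider, so this share cannot decide whether the number exceeds chance. All 10 outlying values were in pair D or pair G. Pair G was the highest of the 7 pairs for G2/M cell cycle genes (median log2 difference 2.73), DNA replication genes (1.95), nucleotide and polyamine synthesis genes (2.72) and neutrophil and inflammatory chemokine genes (3.03). It was also the highest for MCM4, a replicative helicase subunit gene (2.18), and CXCL3, a chemokine gene (4.21). Pair D was the highest for ESAM, an endothelial adhesion gene (4.23), SDC1, which encodes syndecan 1 (1.98), and IFIT3, an interferon-induced gene (4.62), and the lowest for CDX1, an intestinal transcription factor gene (-2.04). ESAM and IFIT3 were listed at 0 RPKM in the shallow normal mucosa library of pair D.

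The changes were wider in pairs D and G, with SDs of 1.49 and 1.39, than in the 5 other pairs. Over 1624 genes with a mean RPKM of at least 50, where counting error should be smaller, the SD of pair D was 1.75. This was 1.91 times that of the widest of the 5 other pairs, which argues against the low depth of pair D's normal mucosa as the sole cause. The mean was taken over all 14 libraries and that library's counting error was not measured, so a part for depth stays possible. Neither library of pair G was shallow, the lower relative depth being 1.13. Swapped tissue labels in the 5 other pairs would turn the sign and keep the size of their changes, and the widest of them reached 0.527 of the SD of pair G. Little adenoma tissue in the adenoma samples of the 5 other pairs stays open: 5 of the 10 correlations across genes with the changes of pair D or pair G were above 0, and a sample with no adenoma tissue at all may give either sign. The design names no subtype of adenoma, so no biological explanation was tested.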

How the results depend on the processing

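The settings that keep features with a failed status, leave out short structural RNAs or leave out pairs C and E were chosen after seeing the data. The counts of genes higher and lower, with and without a 2-fold limit, were 0 under each of the 20 alternatives. For the sign-flip test this was nearly fixed in advance by its smallest p of 0.0156. Without the pair block the smallest adjusted p was 0.999, and the counts stayed at 0 and 0. No replicate block gave 5 lists higher and 11 lower, against 5 and 9, and passed 2 lists more: goblet cell genes (-0.45) and T and NK cell genes (-0.38). Lists higher in adenoma numbered 1 with per-library weights, that of fatty acid oxidation, and 0 with an estimated correlation or fry, and 3 to 7 with single pairs left out. Lists lower numbered 12 with per-library weights. There the lists of DNA replication, ribosome biogenesis, nucleotide synthesis, gastric, prostaglandin, fibroblast, endothelial, T and NK cell and plasma cell genes came past the threshold as lower, and those of absorptive, BEST4, sodium transport, metallothionein, pan-epithelial and immediate early genes lost their call. Lists lower numbered 0 with an estimated correlation or fry, and 7 to 12 with single pairs left out. Leaving out a pair whose median opposed or fell short of the others moves a list towards passing in any case. The passes given with single pairs left out used the preset correlation, so they are no added evidence for a list. With per-library weights, pairs D and G carried the least weight (0.217 and 0.271, against 0.779 to 3.57 in the others). Both libraries of a pair received the same weight, because with the pair as a block their residuals mirror each other. The weights thus reflect how far a pair's changes departed from the mean change, and cannot single out a poor library. The cause of the other moves was not tested.

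The spread ratio was not past the threshold under any alternative. It was -0.0123 with an RPKM floor of 5, -0.0226 with median centring, -0.0146 with quantile normalization and -0.0152 with the median absolute deviation, and -0.15 to 0.11 with single pairs left out. The relation of Wnt target and absorptive genes had r of -0.922 without pairs C and E (exact permutation p = 0.0667, n = 5) and -0.939 to -0.856 with single pairs left out. That of Wnt target and G2/M genes had r of 0.504 to 0.940 with single pairs left out.

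For named genes, 1860 values kept their direction and 37 turned. For list medians, 451 kept direction and side, 30 came past the threshold, 17 lost it and 62 turned. Each median was put in 1 class, so medians that turned and also passed or lost the threshold count only as turned. With per-library weights the difference turned for GINS1 (-0.082), GAR1 (-0.021), POLR1B (-0.0102), UTP20 (-0.10), SHMT2 (-0.085), ZG16 (0.44), ACAT1 (0.03), ACAA2 (0.30), ADM (0.022), NDRG1 (0.23), HK2 (0.029), MT1H (0.21), MT1G (0.13), LUM (-0.99), VWF (-0.13), ESAM (-0.24), TPSB2 (-0.18), IFIT3 (-0.16), DUSP1 (0.016) and MYC (-0.051). So did the medians of the lists of DNA replication (-0.13), ribosome biogenesis (-0.20), nucleotide synthesis (-0.21), absorptive colonocyte (0.23), goblet cell (0.24), Paneth and REG (-0.12), gastric (-0.58), pan-epithelial (0.033), MAPK output (-0.067), prostaglandin (-0.10), fatty acid oxidation (0.29), sodium transport (0.068), glycolysis (0.029), metallothionein (0.14), endothelial (-0.33), neutrophil (-0.027), mast cell (-0.15) and immediate early genes (0.039). Without pairs C and E, LUM (-0.10), VWF (-0.044) and the gastric (-0.13), fatty acid oxidation (0.060), endothelial (-0.091) and interferon (0.13) medians turned, and the fibroblast (-0.41), T and NK cell (-0.77) and plasma cell (-0.42) lists came past the threshold as lower. The prostaglandin median turned with pseudocounts of 0.1 (-0.018) and 5 (-0.022), no filter (-0.080), centring (-0.017) and quantile normalization (-0.018). Others that turned were MAPK output (-0.093) and interferon genes (0.030) with the floor of 5, gastric genes (-0.0052) with centring, fibroblast genes (0.036) with quantile normalization, mast cell genes (-0.00030) with a pseudocount of 5, and neutrophil (-0.16) and interferon genes (0.048) with no filter.

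With single pairs left out, the range crossed 0 for REG4 (-0.24 to 1.55), LUM (-0.21 to 0.92), ESAM (-0.15 to 0.68), S100B (-0.60 to 0.088), GZMA (-0.96 to 0.032), BANK1 (-0.58 to 0.089), CXCL3 (-0.17 to 0.67), TPSB2 (-0.16 to 0.55), CPA3 (-0.37 to 0.14) and IFIT3 (-0.16 to 0.85). It also did for the lists of DNA replication (-0.10 to 0.34), nucleotide synthesis (-0.13 to 0.45), Paneth and REG (-0.082 to 0.30), gastric (-0.31 to 0.26), MAPK output (-0.088 to 0.39), prostaglandin (-0.19 to 0.12), fatty acid oxidation (-0.24 to 0.015), fibroblast (-0.45 to 0.24), endothelial (-0.12 to 0.31), T and NK cell (-0.72 to 0.016), plasma cell (-0.59 to 0.084), neutrophil (-0.31 to 0.67), mast cell (-0.14 to 0.43) and interferon genes (-0.34 to 0.31). The relative depth of 0.039 in pair D's normal mucosa limits its low genes. Values without pair D enter these ranges, but ranges that did not cross 0, such as those of LGR5 and the Wnt target list, are not given here. Fits to counts were not run.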

Other observations

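The test of histone genes was written before its result was seen, and the other tests here afterwards. B cell genes, too few for a list test, differed between pairs in both directions. CD79B, a B cell receptor component gene, had 12.8 RPKM in the normal mucosa and 0.187 RPKM in the adenoma of pair A, and 12.6 against 0.646 RPKM in pair G, but 1.64 against 10.3 RPKM in pair E. BANK1, a B cell scaffold gene, had 4.23 against 0.153 RPKM in pair A and 3.10 against 12.8 RPKM in pair E. The authors' deposited tables called FDCSP, a follicular dendritic cell gene, in 3 pairs, higher in pair C and lower in pairs F and G. It had 51.1 RPKM in the normal mucosa of pair G and was listed at 0 in its adenoma, while in pair E it had 1.78 against 36.9 RPKM. REG4, a secreted lectin gene of the Paneth list, had 3.88 against 362 RPKM in pair G and 2110 against 92.0 RPKM in pair B.

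Calls of the authors' deposited tables overlapped between some pairs. Pairs B and F shared 16 calls of the same direction, where 0.374 would be expected of independent lists, pairs A and B shared 10 (0.177) and pairs A and F shared 7 (0.156). Pairs E and F shared 10 calls of opposite direction and 0 of the same. These pairs share no library. Across genes, which are not independent replicates, the changes of pairs E and F had a correlation of -0.497 and those of pairs A and F of 0.442.

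In pairs C and E, short structural RNAs took 73.4% to 93.7% of the summed RPKM, against at most 31.1% in the 10 other libraries. RPKM is scaled by feature length, so these are not shares of reads. Low depth in pairs C and E does not account for the high share, since 2 other libraries were shallower than every library of these pairs. The length correction of features shorter than a fragment stays open. 7SK, RMRP and RPPH1, each over 250 bases, were also high, and the lowest ratio of their RPKM to the RPKM without short structural RNAs in pairs C and E was 1579 times the highest in the 10 other libraries. These RNAs are members of the set that makes up the structural RNA share, and the fragment length is not given, so this does not decide. A weaker selection of polyadenylated RNA in pairs C and E may account for it. Transcripts of replication-dependent histone genes lack poly(A), and the 73 listed made up 0.960% to 4.73% of the RPKM without short structural RNAs in these 4 libraries, and 0.0269% to 0.193% in the others, the lowest of the former being 4.97 times the highest of the latter. Both tissues of a pair shared the feature, so it lies between pairs and not between tissues.

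Chance could not be excluded for the counts of genes at an unadjusted p under 0.05 and of lists. Of the 64 splits that part all 7 pairs, 42 gave as many genes at an unadjusted p under 0.05 as the real 249, and the highest other gave 1691. For lists past camera with a preset correlation, 32 of the 64 splits gave as many as the real 14, and the highest other gave 24, so a count of 14 such lists is what splits of these pairs commonly give. For genes past adjusted p 0.05 the real split gave 0, so 64 of 64 such splits, and 100 of 100 splits drawn without the block, give as many by construction, and these counts say nothing about chance. The highest other gave 1 with the block and 797 without it, and the latter points to a structure of the samples. Of the 3 drawn splits with over 10 genes, 2 had the 4 libraries of pairs C and E on the same side and the one with 797 had 3 of them, whereas 9 of the 100 drawn splits had 4 together.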
